A study of Mus musculus with 18 samples.

How the data were processed

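Frozen brains of newborn mice (postnatal day 0) were dissected into frontal regions by the submitters, RNA was extracted, and cDNA was made with a low-input whole-transcript kit (SMART-seq v4) and turned into libraries with Nextera XT, which were sequenced as 100 bp read pairs. The deposited table holds raw counts of fragments per gene, not normalized. Per the file headers, they were counted by featureCounts 1.6.2 in pairs, ignoring strand, against the Ensembl 94 gene models of mouse genome GRCm38, and per the submitters' processing notes the reads were aligned with STAR 2.6. No option for reads with several alignments appears in the recorded command. Of its columns of per-sample values, 18 matched the samples and were used, and 6 matched no sample and were not read. Gene symbols were matched by Ensembl identifier to GENCODE mouse release M21 for 54409 of 54532 genes.

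The 18 libraries form 6 groups of 3 (orbital, medial and dorsal tissue of control and dKO pups). Gene-level totals were 28957325 to 93093398 fragments per library. The title prefix and the index of each library define 6 rows of 3 regions and 3 sets of 1 control and 1 dKO row. The labels do not state how many animals were used or whether the libraries of a row come from a single brain, so p-values measure only the spread between these samples. Sex, litter and the altered exons are not given in the labels.

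Counts were analysed in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr with a minimum count of 10 and a minimum total of 15, quasi-likelihood F tests), and p-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. Each region was tested as dKO minus control in a fit of 6 group means and the title prefix (18730 genes). This fit held no term for the row, so the 3 libraries of a row counted as independent when the spread was estimated. Counts summed over the regions of a row were tested with the title prefix as a covariate (20083 genes). Region differences in controls and in dKO, and the difference of the dKO effect between regions, were tested in a fit with the row as a block. Standard errors are those of the fitted log2 fold change, and CPM values are given as mean and SD of 3 libraries. Values within a set are differences of log2 CPM with a prior count of 2.

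Named genes were chosen by a rule fixed before the data were examined. Per dKO comparison these were the 12 rising and 12 falling genes with the lowest p among those past the threshold, with a mean of at least 1 CPM, the same sign in the 3 sets and a symbol that is not a predicted gene, Y-linked or Xist. Where fewer than 5 passed in a direction, the 5 with the lowest p were taken instead, by the same limits. Some genes chosen by these rules are not reported here. For regions in controls 8 per direction were taken, for the interaction 8 in all, and for each list that passed or had a changed member up to 4 members. Also before the data were examined, 36 gene lists were fixed, covering retinoic acid signalling, cortical layers and areas, guidance and adhesion, synapses, progenitors, other cell types, stress and mitochondria. Lists were tested with camera of limma 3.58.1 (preset correlation 0.01), again with an estimated correlation, and with fry, and adjusted over the lists. Members were counted at adjusted p over all genes and over the list alone. Intervals and p-values treat a list's genes as sampled from the same libraries, and lists share some genes.

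Regional retention used genes chosen in the controls of the other 2 sets with a mean of at least 5 CPM, 100 per direction, and an exact sign-flip permutation test over the 3 sets. Correlations of fold changes were set beside those of the other 9 splits of the 6 rows. Genes within 10 Mb of Rarb or Rxrg were compared with the rest by Fisher's exact test. Alternatives were other size factors, no filter, DESeq2 1.42.0, limma-voom, other terms for batch, a stricter threshold of 0.01, the spread of a region's own libraries and leaving out each library or row. Covariates for progenitor score and for sex and a restriction to autosomes were added after the data were seen. Figures were drawn with matplotlib 3.10.9.

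The fits were tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. The region fits recovered 45% and 82% of these in orbital, 43% and 87% in medial and 44% and 83% in dorsal comparisons, the summed fit 83% and 99%, the control comparisons 29% to 34% and 86% to 87%, and the test of the difference between regions 6% and 65%. Between 0 and 10 unchanged genes were called per comparison, and the list test called the 1 list that had been raised and none of the others. Simulated genes varied independently of each other, without differences between rows or sets, and the changed genes were drawn from the more abundant ones. The list result thus does not show how the test behaves where members vary together. In the real data the estimated correlation was 0.425 for cell cycle genes in medial cortex.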

Results

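RNA from the frontal cortex of newborn mice (postnatal day 0) was sequenced in control pups and in double mutants of Rxrg and Rarb (dKO). These genes encode retinoid X receptor gamma and retinoic acid receptor beta, nuclear receptors through which retinoic acid acts on transcription. Samples were taken from 3 regions, given in the labels as orbital, medial and dorsal, so that 18 libraries formed 6 groups of 3. The dissection notes list medial frontal, motor and orbitofrontal tissue, and the labels do not state which of these the dorsal samples are. Gene-level totals ran from 28957325 to 93093398 fragments per library. The index sequences and title prefixes placed the libraries in 3 sets, A, B and C, which are replicates 1, 2 and 3 here, each with 1 control and 1 dKO row of 3 regions. Whether a row came from a single brain is not stated. Set A was deeper, with 70636819 to 93093398 fragments in its controls and 52317649 to 58941490 in its dKO libraries. Sets B and C had 28957325 to 39158792. Replicates of a group differed by 37.9 to 174 times the variance of counting alone (chi-square per degree of freedom).

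Both targeted genes were measured first, since transcripts of a disrupted gene may persist in part. Rarb (ENSMUSG00000017491, GRCm38 chromosome 14, 16430839 to 16819156, minus strand) had 3.50 to 13.9 CPM (counts per 1e6 counted fragments) in the 9 control libraries and 1.19 to 4.85 CPM in the dKO libraries. It was lower in dKO in 9 of 9 pairs of the same set and region, though by little in set A, with 3.50 and 2.96 CPM in control and dKO medial tissue and 3.50 and 3.11 CPM in dorsal tissue. Orbital tissue held 9.16 ± 4.14 CPM of Rarb in controls and 3.43 ± 1.3 CPM in dKO (SD, n = 3), medial tissue 4.41 ± 0.799 and 1.86 ± 0.965, and dorsal tissue 4.77 ± 1.11 and 2.54 ± 0.491. Rxrg (ENSMUSG00000015843, chromosome 1, 167598384 to 167639623, plus strand) had 0.377 to 2.90 CPM in dKO libraries. Its controls were uneven: set B held 21.4 CPM in orbital, 6.12 in medial and 30.5 in dorsal tissue, while sets A and C held 1.64 to 4.01 CPM. Rxrg was lower in dKO in 8 of 9 pairs, the exception being orbital tissue of set A (2.90 CPM in dKO, 2.35 in control). Neither gene passed the test over all genes: with regions summed, the log2 fold change was -1.33 for Rarb (SE 0.313, adjusted p = 0.365) and -2.50 for Rxrg (SE 0.887, adjusted p = 0.479). Rarb passed with DESeq2 in the summed data (-1.31, SE 0.318, adjusted p = 0.00602), where its adjusted p over all alternatives ran from 0.00343 to 1. For Rxrg the lowest adjusted p over the alternatives (edgeR, DESeq2 and limma-voom) was 0.026 in the summed data and 0.015 in dorsal tissue. Its summed log2 fold change ran from -7.06 to -1.225 over these. The difference between dKO and control was much smaller in set A: the mean over the 3 regions of the log2 CPM difference was -0.49, -1.70 and -1.55 for Rarb and -0.53, -3.33 and -2.71 for Rxrg in sets A, B and C. For Rxrg the larger difference in set B lay in its high controls. Its dKO libraries held 1.33 to 1.69 CPM in set B, within the 1.05 to 2.90 CPM of set A, and 0.377 to 0.691 CPM in set C. The counts cover whole genes, and the labels do not say which exons were altered.

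**Figure D1:**
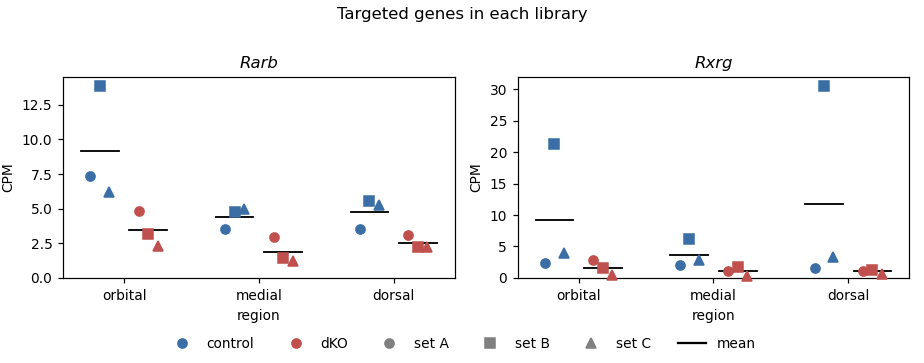
CPM (vertical axes) of Rarb and Rxrg in each of 18 libraries, by region (horizontal axes) and genotype (colour), with the library set as the symbol and a line at the mean of 3. Rarb was lower in dKO in 9 of 9 pairs, least in medial and dorsal tissue of set A, and the Rxrg controls of set B (21.4 and 30.5 CPM in orbital and dorsal tissue) stood above those of sets A and C.

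The sex of the pups was not given in the labels and differed between genotypes. Xist, the transcript of the inactive X chromosome, was at 9.45 to 31.4 CPM in the dKO libraries of sets A and C and at most 0.155 CPM in the other libraries. The Y-linked gene Ddx3y was at 58.3 to 119 CPM in all controls and in the dKO libraries of set B, and at most 0.203 CPM in the dKO libraries of sets A and C. Set B therefore compared male with male tissue, and sets A and C compared female dKO with male control tissue.

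Medial cortex held the most changed genes in dKO: 221 rose and 168 fell of 18730 tested, 234 of them at least 2-fold. Among those that rose were genes of mitosis. Cdk1, the kinase that starts mitosis, went from 12.0 ± 1.27 to 32.8 ± 4.27 CPM (SD, n = 3; log2 fold change 1.37, SE 0.180, adjusted p = 0.0026). Cdc20, an activator of the anaphase-promoting complex, rose by 1.49 on the log2 scale (SE 0.205), the mitotic kinase gene Pbk by 1.70 (SE 0.230), the spindle protein gene Nusap1 by 1.54 (SE 0.218), and Cenpa, the histone of centromeres, by 1.6 (SE 0.231). Fam210b rose by 1.89 (SE 0.218, adjusted p = 0.00107; 1.12, 2.15 and 2.40 in sets A, B and C). Ptx3 rose by 2.12, Mfng, which modifies Notch receptors, by 1.85, the membrane linker gene Ezr by 1.78, Ccn1 by 1.58, the cyclin-dependent kinase inhibitor gene Cdkn2c by 1.44 and Csrp1 by 1.27. Among those that fell, Syn2, a protein of synaptic vesicles, went from 117 ± 18.6 to 58.7 ± 2.47 CPM (log2 fold change -1.08, SE 0.153, adjusted p = 0.00287; -0.92, -1.33 and -0.94 in sets A, B and C). Hmgcs1, of the cholesterol pathway, went from 954 ± 136 to 469 ± 91.4 CPM (-1.12, SE 0.159). The log2 fold change was -1.18 for the guanylate cyclase subunit gene Gucy1b1, -0.95 for Rtn4, -1.12 for Necab1, -1.16 for Far2, -1.01 for Impdh1, which makes guanine nucleotides, -1.0 for Rap1gds1, -1.24 for Ccdc184, -0.98 for Phf24 and -0.97 for Gmip.

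By the fixed lists, 24 cell cycle genes were measured in medial cortex, and 13 rose with adjustment over all genes (21 adjusted over the list alone). The list rose as a whole (camera adjusted p = 1.74e-22, adjusted p = 0.121 with an estimated correlation), with Aurka at 1.57 and Bub1b at 1.81 beside Cdk1 and Cdc20. Of 19 genes of radial glia and intermediate progenitors, the dividing cells of the embryonic cortex, 6 rose over all genes tested and, adjusted over the list alone, 12 rose and 1 fell (camera adjusted p = 2.19e-09, adjusted p = 0.121 with an estimated correlation). Pax6, a transcription factor of radial glia, rose by 2.46 (SE 0.378, adjusted p = 0.00449), Vim by 0.82, Gas1 by 1.40, and Eomes, of intermediate progenitors, from at most 0.881 CPM in medial controls to 9.90 to 26.1 CPM. In the same libraries microglia markers rose as a list (median log2 fold change 0.42, none of 16 over all genes and 3 adjusted over the list alone; camera adjusted p = 0.000967, adjusted p = 0.464 with an estimated correlation). Astrocyte markers did too (median 0.21, camera adjusted p = 0.0192, adjusted p = 0.570 with an estimated correlation), with 2 of 18 past the test over all genes, Aldoc at 1.22 and Mlc1 at 1.29, and 5 adjusted over the list alone.

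The synaptic lists fell in medial cortex. Of 25 genes of presynaptic release, 6 fell over all genes tested and 14 adjusted over the list alone (camera adjusted p = 2.88e-08, adjusted p = 0.121 with an estimated correlation). They included the calcium sensor of release Syt1 (-0.89), Sv2b (-1.22) and Syn1 (-0.78). Of 36 glutamate receptor and postsynaptic genes, 2 fell over all genes, Grm7 (-1.46, SE 0.293) and Grin3a (-1.15, SE 0.266), and 4 adjusted over the list alone (camera adjusted p = 4.1e-09, adjusted p = 0.310 with an estimated correlation). Of 32 synaptic organizers, 1 fell over all genes and 4 adjusted over the list alone (camera adjusted p = 1.45e-05, adjusted p = 0.310 with an estimated correlation). Genes of cytosolic ribosomal proteins (median 0.35, camera adjusted p = 3.86e-07), mitochondrially encoded genes (0.57, adjusted p = 0.000132) and nuclear genes of the respiratory chain (0.23, adjusted p = 0.027) rose as lists. None of their members passed over all genes or over the list alone, and adjusted p was 0.613, 0.570 and 0.766 with an estimated correlation. The retinoic acid pathway list did not pass (median -0.05, mean -0.07, camera direction up, adjusted p = 0.983; 1 gene higher and 1 lower adjusted over the list alone, the lower being the targeted Rarb). Members of lists that did not pass included Lhx2 (1.07, adjusted p = 0.0318), the semaphorin gene Sema5b (1.51, adjusted p = 0.022), Plxnd1, a semaphorin receptor (-1.43, adjusted p = 0.0296), Rprm of layer 6 (-0.77, adjusted p = 0.0207) and Ephb6 (-0.98, adjusted p = 0.0462).

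**Figure D2:**
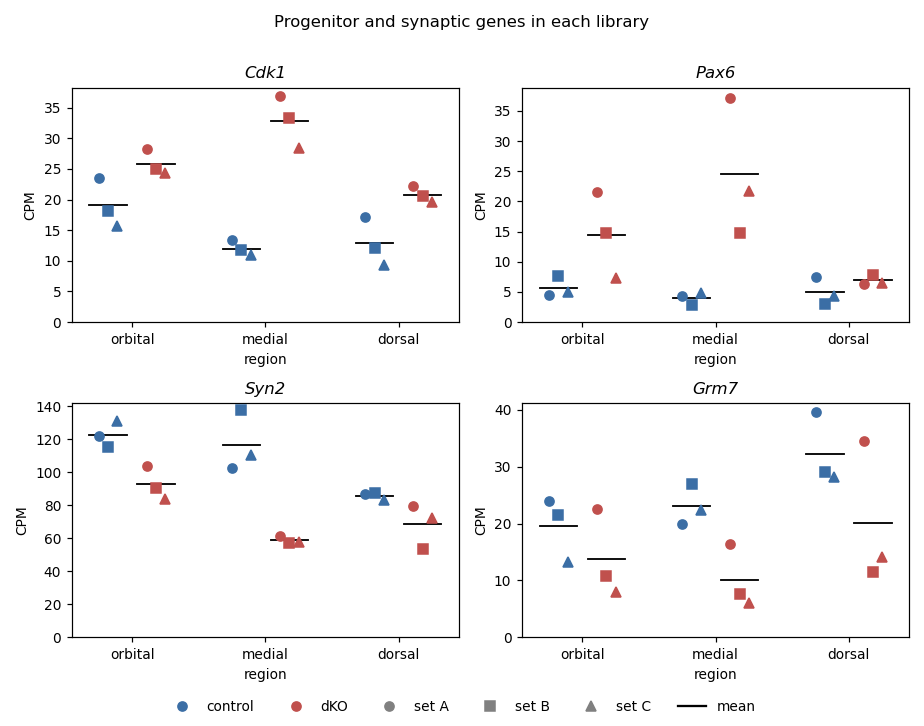
CPM (vertical axes) of Cdk1, Pax6, Syn2 and Grm7 in each library, by region (horizontal axes), genotype (colour) and set (symbol), with a line at the mean of 3. In medial tissue the 3 dKO libraries lay above the 3 controls for Cdk1 (means 32.8 and 12.0 CPM) and Pax6, and below them for Syn2 (means 58.7 and 117 CPM) and Grm7.

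Of the 389 genes changed in medial dKO, 13 lay on the X chromosome, where 610 X-linked genes were tested. The count moved when most single medial libraries were left out: it was 122, 158, 67, 107 and 133 without control replicate 2, control replicate 3, dKO replicate 1, dKO replicate 2 and dKO replicate 3, and 362 without control replicate 1. Of those 362, 174 were higher and 188 lower, and 222 were among the 389. Of the named genes Gmip lost its call without dKO replicate 1 or 2 (adjusted p = 0.0582 and 0.0541; 3.88e-06 to 0.129 over all alternatives). The count was 31 when the spread was taken from the 6 medial libraries alone and 1118 with DESeq2. It was 1 (4247 at unadjusted p under 0.05) with a score of progenitor and cell cycle genes as a covariate, a setting added after the data were seen, in which the score and the genotype overlap in medial tissue. With sex as a covariate, also added after the data were seen, it was 156, of which 130 were among the 389.

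Orbital cortex had 7 genes past the test, 2605 at unadjusted p under 0.05. Prss56, a serine protease gene, went from 18.8 ± 24 to 0.137 ± 0.0715 CPM (SD, n = 3; log2 fold change -6.34, SE 0.963, adjusted p = 0.0224; -8.46, -5.63 and -3.29 in sets A, B and C). The teneurin gene Tenm4 rose from 20.9 ± 3.65 to 63.6 ± 29 CPM (1.54, SE 0.258, adjusted p = 0.049). Also past the test were the predicted genes Gm10704, Gm10340, Gm3373 and Gm6356, all higher in dKO, outside the rule for named genes and singled out after their values were seen. Not past the test, with the lowest p, were Ddx3x (1.12, SE 0.199), Lipg (1.5, SE 0.266), Rbm33 (0.89, SE 0.160), Zpld1 (-5.57, SE 0.963), Anxa5 (-1.10, SE 0.192) and Cd82 (-1.16, SE 0.206), at adjusted p from 0.0579 to 0.0617, and Pcdhga6 (1.28, adjusted p = 0.125). Prss56 no longer passed without control replicates 1 or 2 or dKO replicates 1 or 2 (adjusted p = 0.123, 0.0714, 0.117 and 0.168). Nor did Tenm4 without any orbital library but dKO replicate 3 (0.0652 to 0.389). Over all alternatives the adjusted p ran from 4.49e-08 to 0.527 for Prss56 and from 2.06e-05 to 0.630 for Tenm4, with the sign kept in each.

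The lists that passed in orbital dKO did so without members past the test over all genes. Of the 24 measured members of the retinoic acid pathway, 5 had positive and the rest negative fold changes, and the list fell (median -0.42, camera adjusted p = 0.0188, adjusted p = 0.487 with an estimated correlation; 2 lower adjusted over the list alone). The list holds the targeted genes Rarb and Rxrg and was not tested without them. Its largest shifts by p were Rarb itself (-1.44, SE 0.365), the retinoic acid binding protein gene Crabp2 (-1.53, SE 0.424), Rarg (-0.97, SE 0.345) and the retinol transporter gene Stra6 (-1.08, SE 0.393). Crabp2 is also in the meningeal list, and meningeal fibroblast markers (median -0.63, camera adjusted p = 0.000457, 3 of 20 lower adjusted over the list alone) and microglia markers (median -0.59, camera adjusted p = 0.000457) fell in the same libraries, with adjusted p = 0.487 for each with an estimated correlation. Lists of axon guidance and adhesion rose: semaphorins, plexins and neuropilins (median 0.32, camera adjusted p = 0.000457), and netrin, slit, robo and related genes (0.40, adjusted p = 0.00113). So did cadherins and protocadherins (0.38, adjusted p = 0.000531), synaptic organizers (0.21, adjusted p = 0.00386) and upper layer markers (0.34, adjusted p = 0.0172). Each was at adjusted p = 0.487 with an estimated correlation. Their members with the lowest p were Sema5b (1.27, SE 0.311), Flrt2 (0.95, SE 0.219), Cdh2 (0.70, SE 0.170), Ptprs (0.83, SE 0.206) and Lhx2 (1.15, SE 0.242), at adjusted p from 0.129 to 0.148. Cell cycle genes rose as a list (median 0.57, camera adjusted p = 4.36e-06, adjusted p = 0.487 with an estimated correlation), with 23 of 24 positive. Mitochondrially encoded genes rose (median 0.47, camera adjusted p = 0.0011, adjusted p = 0.487 with an estimated correlation) and nuclear genes of the respiratory chain fell (-0.37, camera adjusted p = 0.000464, adjusted p = 0.608 with an estimated correlation). The count of orbital genes was 3 without control replicate 1, 4 without dKO replicate 1, 2 with the spread of the 6 orbital libraries alone and 430 with DESeq2.

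**Figure D3:**
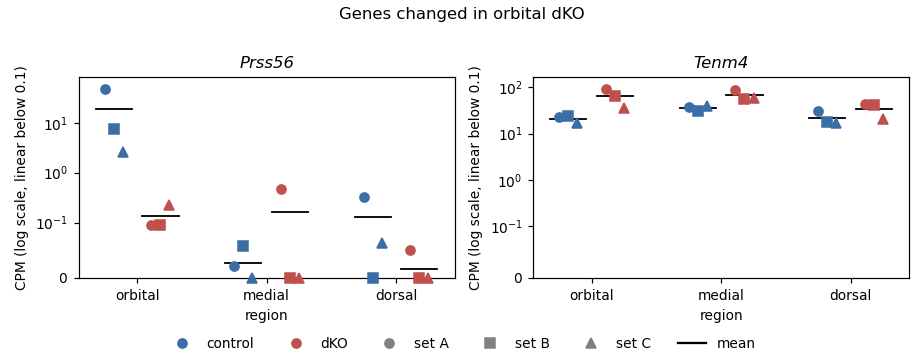
CPM (vertical axes, logarithmic above 0.1 and linear below) of Prss56 and Tenm4 in each library, by region (horizontal axes), genotype (colour) and set (symbol), with a line at the mean of 3. The orbital controls spread from 2.58 to 46.4 CPM for Prss56, and the mean of Tenm4 in orbital tissue was 20.9 CPM in controls and 63.6 in dKO.

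In dorsal cortex the genes past the test were the same 4 predicted genes, all higher, with 1270 genes at unadjusted p under 0.05. Named genes with the lowest p did not pass: the glucose transporter gene Slc2a4 (1.31, SE 0.255, adjusted p = 0.234), Fam180a (1.86), Cdc20 (0.92, SE 0.204), Pdgfrl (0.88), C1qtnf7 (1.64), Impdh1 (-0.85, SE 0.160, adjusted p = 0.223), Hmgcs1 (-0.79, SE 0.158), Ydjc (-0.94), Mgat4c (-0.97) and B4galt5 (-0.78). Cell cycle genes rose as a list in dorsal dKO (median 0.71, 7 of 24 higher adjusted over the list alone and none over all genes; camera adjusted p = 1.4e-09, adjusted p = 0.569 with an estimated correlation). Genes of glutamate receptors (median -0.32, camera adjusted p = 2.62e-06), presynaptic release (-0.25, adjusted p = 0.000533) and synaptic organizers (-0.33, adjusted p = 0.000533; Cbln2 lowest at -2.02, SE 0.529) fell as lists, each at adjusted p = 0.569 with an estimated correlation. Markers of striatal projection neurons fell (-0.30, camera adjusted p = 0.00942), and those of meningeal fibroblasts (0.46, adjusted p = 0.00942) and of endothelial cells and pericytes (0.22, adjusted p = 0.0202) rose, at adjusted p of 0.635, 0.831 and 0.569 with an estimated correlation. The dorsal count was 2 without control replicate 2, control replicate 3 or dKO replicate 3, and 81 with DESeq2.

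With the 3 regions of a row summed, so that each row counted as 1 value, 5 of 20083 genes passed: Prss56 (-5.75, SE 0.600, adjusted p = 0.041) and the same 4 predicted genes. Prss56 averaged 18.8 CPM in orbital controls and at most 0.159 CPM in any other group of region and genotype. Its summed call thus repeats the orbital result and does not show a change in the other regions. Prss56 no longer passed without control row 1, dKO row 1 or dKO row 2 (adjusted p = 0.337, 0.254 and 0.0777; 1.45e-20 to 0.673 over all alternatives). The progenitor factor Pax6 (1.54, SE 0.201, adjusted p = 0.162), Sema5b (1.15, SE 0.151), the growth factor gene Hgf (2.25, SE 0.309), the mitotic kinase gene Nek2 (1.32, SE 0.205) and Fam210b (1.08, SE 0.174) had the lowest p among higher genes without passing. Among lower genes these were Mybpc1 (-5.31), the synaptic organizer gene Cbln2 (-1.42, SE 0.237), Hmgcs1 (-0.77, SE 0.129) and Cyp26b1, which degrades retinoic acid (-1.13, SE 0.191, adjusted p = 0.295). Mybpc1 likewise averaged 12.1 CPM in orbital controls and at most 0.223 CPM in any other group. Cell cycle genes (18 of 24 higher adjusted over the list alone and none over all genes, camera adjusted p = 6.69e-15) and progenitor genes (5 of 19 higher adjusted over the list alone, camera adjusted p = 1.06e-05) rose as lists. Glutamate receptor genes (camera adjusted p = 0.00122) and presynaptic genes (0.00402, 1 of 25 lower adjusted over the list alone) fell, mitochondrially encoded genes rose (0.000367), and the Y-linked list fell (0.0104). With an estimated correlation the adjusted p was 0.742 for the cell cycle, progenitor and presynaptic lists and 0.950 for the others. The retinoic acid pathway list did not pass with regions summed (median -0.11, camera adjusted p = 0.292), and of its 2 members lower adjusted over the list alone, Cyp26b1 and Rarb, the latter is a targeted gene. DESeq2 called 359 genes, and the edgeR count was 8 without control row 2 and 9 without dKO row 2.

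DNA of the line in which a mutation was made stays linked to the mutated gene, so changed genes near Rarb and Rxrg were counted. With regions summed, 1 of 318 genes within 10 Mb of either gene had changed (Gm6356), against 4 of 19763 elsewhere (Fisher's exact test, two-sided, p = 0.0767). Within 20 Mb these were Gm10340, Gm3373 and Gm6356, 3 of 609 against 2 of 19472 (Fisher's exact test, p = 0.000265), and within 5 Mb none of 194 (p = 1; edgeR, 26 at unadjusted p under 0.05). Gm10340, Gm3373 and Gm6356 all lay between 3133997 and 6973818 of chromosome 14. Fisher's exact test counted them as independent, which they may not be, and reads shared between them were not examined. At unadjusted p under 0.05 the summed data held a larger share near the loci than elsewhere. It was 12.6% against 8.97% within 10 Mb and 13.4% against 8.98% within 5 Mb (Fisher's exact test, p = 0.0298 and 0.0426). In medial cortex 9 of 288 genes within 10 Mb had changed, against 380 of 18440 (Fisher's exact test, p = 0.207). At unadjusted p under 0.05 the medial shares were 17% and 15% (Fisher's exact test, p = 0.36).

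The effect of dKO was then compared between regions within rows. It differed for 23 genes of 18730 (F test over regions, 2998 at unadjusted p under 0.05). Mdk, a growth factor gene, was at 1.40 (SE 0.280) in medial, -0.15 (SE 0.275) in orbital and 0.40 (SE 0.276) in dorsal dKO, and Csrp1 at 1.27, -0.16 and 0.50. Flrt2, an adhesion and guidance receptor, was at 0.95 (SE 0.219) in orbital, -0.55 (SE 0.217) in medial and -0.49 (SE 0.218) in dorsal dKO. The fold changes of Smpdl3a, Cd63, Ndrg2, Clic1 and Nupr1 were positive in medial and negative in orbital dKO, as with 0.83 and -0.42 for Ndrg2 and 0.68 and -0.57 for Clic1 (adjusted p = 0.0451 for all 8). By pairs, 275 genes differed in effect between medial and orbital cortex, 128 with the higher effect in medial. None differed between medial and dorsal (edgeR, 969 at unadjusted p under 0.05) or orbital and dorsal cortex (2363 at unadjusted p under 0.05). Of the 221 genes that rose in medial dKO, 211 had a positive fold change in dorsal and 179 in orbital cortex, and of the 168 that fell, 166 and 128 had a negative one. The regions share the same rows, and the share of all genes with the same sign is not given. These counts are therefore not independent evidence of a shared effect.

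Across all 18730 genes, the log2 fold changes in medial and dorsal dKO correlated at Pearson r = 0.487 (Spearman rho = 0.510), orbital and dorsal at 0.348 (0.260), and orbital and medial at 0.317 (0.196). Genes are not independent replicates, and the other 9 splits of the 6 rows gave r of 0.288 to 0.590, 0.272 to 0.595 and 0.274 to 0.532. The test over regions was unstable: it gave 184 genes without control row 1, 1 without control row 3, and 0 without any of the other rows (edgeR, 1517 to 3135 at unadjusted p under 0.05). DESeq2 gave 1217.

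**Figure D4:**
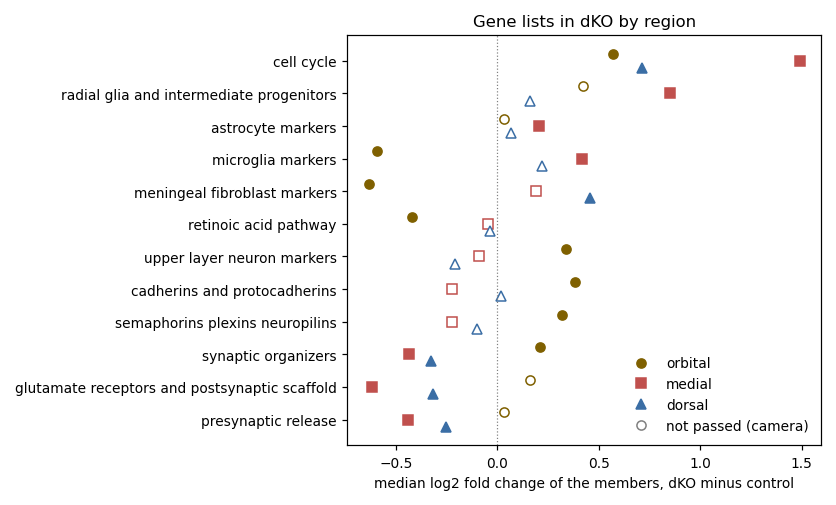
Median log2 fold change of list members (horizontal axis, dKO minus control) for 12 of the fixed lists (vertical axis) in orbital, medial and dorsal tissue, filled where the list passed camera with its preset correlation. Cell cycle genes were above 0 in all 3 regions (0.57, 1.49 and 0.71), while microglia and meningeal markers were negative in orbital tissue (-0.59 and -0.63) and positive in medial and dorsal tissue.

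Regions were compared within control rows as the background for these differences. Between medial and dorsal controls 92 genes differed, 39 higher and 53 lower in medial. Markers of upper layer neurons were lower in medial tissue: 5 of 17 over all genes and 11 adjusted over the list alone, with 1 higher (camera adjusted p = 4.21e-12, adjusted p = 0.128 with an estimated correlation). Cux1 went from 324 ± 57.7 CPM in dorsal to 112 ± 23.1 in medial tissue (SD, n = 3; log2 difference -1.57, SE 0.132), Cux2 differed by -1.50, Mdga1 by -1.99 and Inhba by -2.11. Markers of layer 5 were higher, 2 of 12 over all genes and 4 adjusted over the list alone (camera adjusted p = 0.00497, adjusted p = 0.198 with an estimated correlation), with Crym at 2.70 (SE 0.351) and Fezf2, a factor of subcerebral neurons, at 0.84 (SE 0.152). Endothelial markers were lower as a list (median -0.27, camera adjusted p = 0.00996, adjusted p = 0.712 with an estimated correlation), and no member passed over all genes or over the list alone. Neurod1 (1.62), March1 (1.32), Cadm1 (1.11), Hrk (1.73), Serpini1 (0.70), Stxbp6 (1.17) and Mgat4c (0.96) were higher in medial controls. Pcsk2 (-1.34), Hs6st2 (-1.39), the glutamate receptor gene Grm2 (-1.58), Cdh6 (-1.41) and the retinaldehyde reductase gene Dhrs3 (-1.30) were lower. The count was 17, 42 and 7 without control rows 1, 2 and 3, and 16, 31 and 54 without dKO rows 1, 2 and 3, and it was 1 without the row block.

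Orbital and dorsal controls differed for 2965 genes, 1196 higher and 1769 lower in orbital. Of the upper layer markers 12 of 17 were lower and 1 higher over all genes, 14 and 1 adjusted over the list alone (camera adjusted p = 1.14e-08, adjusted p = 0.340 with an estimated correlation), among them Lhx2 (-1.95, SE 0.2). Of the glutamate receptor genes 18 of 36 were lower, and adjusted over the list alone 25 were lower and 1 higher (camera adjusted p = 1.32e-09, adjusted p = 0.407 with an estimated correlation). Markers of other cell types were higher in orbital controls: microglia (12 of 16, 14 adjusted over the list alone, camera adjusted p = 1.48e-07) and meningeal fibroblasts (11 of 20, 14 adjusted over the list alone, 1.03e-05). So were those of blood (6 of 9, 7 adjusted over the list alone, 0.000233) and choroid plexus (5 of 11, 6 adjusted over the list alone, 0.00335). With an estimated correlation adjusted p was 0.407, 0.510, 0.409 and 0.349. The retinoic acid pathway had 7 genes higher and 3 lower of 24, 9 and 3 adjusted over the list alone (camera adjusted p = 0.0449, adjusted p = 0.510 with an estimated correlation), with the binding protein gene Crabp2 at 1.56 (SE 0.224). Prss56 (6.90, SE 0.846), the tyrosine hydroxylase gene Th (5.95, SE 0.858), Slc22a2 (3.64), H19 (2.06), Apoe (1.21), Cd63 (1.09), Pmp22 (1.07) and Itm2c (0.86) were higher in orbital tissue. Pcsk2 (-1.78), Tbc1d5 (-1.87), Clstn2 (-1.80), Kcnh1 (-1.72), Gucy1a1 (-1.22) and Pde10a (-1.12) were lower. The count was 1857 without dKO row 1, 1430 without control row 2 and 326 without the row block. Without control row 3 it was 923 and the balance turned, with 525 higher and 398 lower.

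Medial and orbital controls differed for 1690 genes, 840 higher and 850 lower in medial. The retinoic acid pathway had 9 genes lower and 1 higher in medial tissue, with the same counts adjusted over the list alone (camera adjusted p = 0.00234, adjusted p = 0.341 with an estimated correlation): Crabp2 (-1.61, SE 0.226), Dhrs3 (-1.48, SE 0.209) and Stra6 (-2.00, SE 0.365). Meningeal markers (10 of 20 lower, 17 adjusted over the list alone, camera adjusted p = 1.05e-09) and microglia markers (9 of 16 lower, 13 adjusted over the list alone, 3.01e-08) were lower in the same tissue, at adjusted p of 0.367 and 0.341 with an estimated correlation. Synaptic organizers (8 of 32 higher, 15 adjusted over the list alone, camera adjusted p = 6.67e-07) and glutamate receptor genes (8 of 36 higher, 19 adjusted over the list alone, 4.25e-08) were higher, at adjusted p of 0.341 and 0.346 with an estimated correlation. Rasgrf2 (2.15), Lipg (2.29), Nkain3 (1.49), Tmem74 (1.03), Cxxc4 (1.03) and Dzip3 (0.91) were higher in medial tissue. Prss56 (-9.64), Mfap4 (-1.49), Pmp22 (-1.18), Apoe (-1.17), Ccnd3 (-0.94) and Ndrg2 (-0.91) were lower. The count was 599 without dKO row 1, 607 without control row 2 and 19 without the row block. The balance of directions rested on single rows: without control row 3, 86 genes were higher and 638 lower (724 in all), and without control row 1, 890 were higher and 329 lower.

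Whether regional differences were as large in dKO as in controls was asked with genes chosen in controls of the other sets, 100 per direction. Orbital and dorsal tissue differed on these genes by a mean log2 of 1.28 ± 0.137 in held-out controls and 0.564 ± 0.334 in dKO (SD, n = 3 sets), smaller in 3 of 3 sets (exact sign-flip permutation test, two-sided, p = 0.25, the smallest it can give). Medial and orbital tissue differed by 0.877 ± 0.158 and 0.0544 ± 0.437, also smaller in 3 of 3 sets (exact sign-flip permutation p = 0.25). Medial and dorsal tissue differed by 0.624 ± 0.146 and 0.711 ± 0.0658, smaller in 2 of 3 sets (exact sign-flip permutation p = 1). These results depended on where the genes were chosen. With genes chosen in dKO of the other sets, medial and orbital tissue differed by 0.518, 0.0509 and -0.339 in controls of sets A, B and C and by 0.628, 0.348 and 0.385 in dKO, so that controls had the smaller difference in 3 of 3 sets. The same held for medial and dorsal tissue (ratios of control to dKO difference of 0.739, 0.465 and 0.525), while orbital and dorsal tissue gave ratios of 0.575, 1.27 and 1. Within dKO rows, 91 genes differed between orbital and dorsal, 392 between medial and dorsal, and 3 between medial and orbital tissue, where the interaction test had passed for 275 genes.

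**Figure D5:**
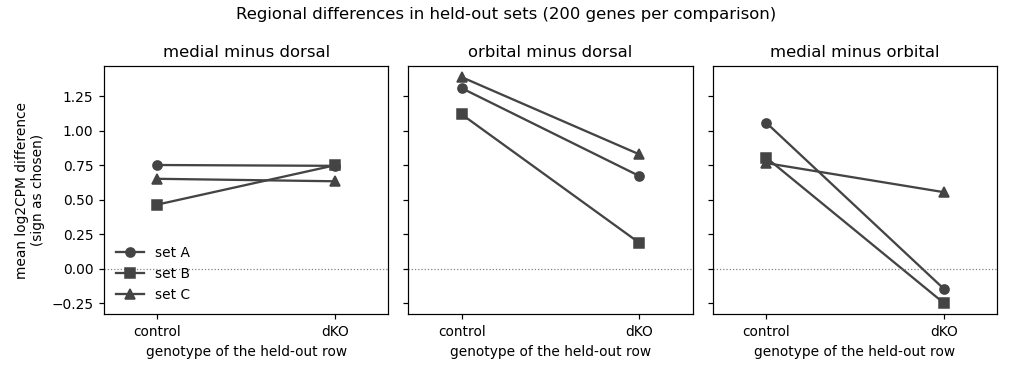
Mean log2 difference between regions (vertical axes, signed as in the controls in which the genes were chosen) for 200 genes per region pair, in the held-out control and dKO row (horizontal axes) of each set. The orbital minus dorsal difference was smaller in dKO in 3 of 3 sets, with means of 1.28 and 0.564.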

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

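The tests for ventricular zone tissue, and for sex as the source of the Prss56 difference, were chosen only after the results were seen, as were the covariates for sex and progenitor score. A difference of the dKO effect between regions drew attention by a test of the difference itself: 23 genes by the test over all regions and 275 between medial and orbital cortex. The test over all regions gave 0 genes with other size factors (edgeR, 3018 at unadjusted p under 0.05) and 1217 with DESeq2. Alternatives were not run for the 275.

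Each dKO count was set beside the other splits of the same 6 libraries or rows. With 10 splits the share cannot fall under 0.05. The real count and the highest of the other splits were 7 and 0 in orbital, 389 and 0 in medial and 4 and 0 in dorsal cortex, and 23 and 0 for the effect that differs between regions, so that 1 of the 10 splits, the real one, gave a count as large. With regions summed they were 5 and 11, with 3 of 10 splits as large, and the highest set both rows of set A and the control row of set B against the rest. With the title prefix in the fit, set A then added nothing to the contrast. That split therefore compared the control row of set B with the other rows of sets B and C, unlike the real split. In controls they were 2965 and 5 for orbital and dorsal, 1690 and 227 for medial and orbital, and 92 and 517 for medial and dorsal tissue, where 2 of 10 splits gave as many genes. The split with 517 genes set medial tissue of set A and both libraries of set B against the rest. The libraries compared in set B, and those in set C, thus lay on the same side as each other. With the row as a block, the contrast in these rows ran only through the orbital libraries. What gave the 517 genes was not tested.

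The rise of cell cycle and progenitor genes and fall of synaptic genes in medial dKO had several candidate explanations. Sex of the pups and depth of the set A controls are argued against as whole causes, though only weakly. Of 200 genes chosen in sets A and C, 91.5% had the same direction in set B, where both genotypes expressed Y-linked genes. The lower share over held-out sets B and C, which have like depths, was 88.5%. These genes vary together, and a held-out set is 1 control and 1 dKO library. Each share is therefore close to a single observation, and shares for other splits are not given. Sex as a covariate took the count from 389 to 156 genes, 130 of them shared. More ventricular zone tissue in the dKO dissections stays open: of the 6 most abundant radial glia genes, 4 (Fabp7, Slc1a3, Vim and Gas1) were higher in every set, while Ptprz1 and Tnc were lower in set B (-0.53 and -1.04). Of the 4, Slc1a3 was higher by only 0.0554 and 0.205 in sets B and C, and Fabp7 by 0.196 in set C. Dilution of neurons by ventricular zone tissue also stays open, as lower genes fell beyond layer markers by a gap of -0.425 at the smallest, between the bounds set beforehand. With the progenitor score as a covariate Syn2 moved from -1.08 (SE 0.153) to -1.10 (SE 0.312), so its call ended through the wider error (adjusted p = 0.0754; 1.35e-08 to 0.0754 over all alternatives), while Cdk1, which is itself part of the score and so falls with it by construction, moved from 1.37 (SE 0.180) to 1.01 (SE 0.353, adjusted p = 0.109; 9.55e-12 to 0.109 over all alternatives) and is not weighed. An effect of genotype on progenitors may exist but was not told apart from dissection here.

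For the lower Prss56 in orbital dKO, a candidate explanation is olfactory ensheathing glia, from tissue near the olfactory bulb, in the orbital control samples: of 9 other genes of these cells listed before the test, 6 were measured, with a median log2 fold change of -1.06 in orbital dKO. The most abundant were Frzb (30.5 CPM in controls, 14.4 in dKO), Sox10 (12.1 and 7.94, also in the oligodendrocyte list) and Matn4 (11.9 and 3.96), and none passed the test over all genes (adjusted p from 0.152 for Matn4). Sox10, Erbb3 and Matn4 were lower in dKO in every set. The others were not: Frzb was higher in set C (log2 difference 0.29), Ngfr in set B (0.205) and Cdh19 in sets B and C (2.2 and 0.0699). Sex as the whole cause is argued against, since in set B, with Y-linked transcripts in both genotypes, the log2 change was -5.63. With sex as a covariate the log2 fold change moved from -6.34 (SE 0.963) to -6.68 (SE 1.36), and the call ended through the wider error (adjusted p = 0.0824; 4.49e-08 to 0.527 over all alternatives). An effect of genotype on these cells was not tested and stays open.

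On genes chosen in controls, orbital and dorsal tissue differed less in dKO. Selection of genes in the same control libraries is argued against, with a ratio of dKO to control difference of at most 0.597 over the held-out sets, and sex with a ratio of 0.168 in set B. When genes were chosen in dKO instead, the ratio of control to dKO difference was 0.575, 1.27 and 1 in sets A, B and C, so the difference in dKO was clearly smaller in set B alone and an effect of where the genes were chosen stays open. Surface or bulb tissue in the orbital controls stays open. The orbital-low genes also came closer, with an observed ratio of at most 0.629, below the bound set beforehand to count against such tissue. But CPM are relative, and synaptic lists were lower in orbital controls in which meningeal and microglia markers were higher, so such tissue could lower these genes as well. Differences in dissection and an effect of genotype cannot be told apart for the orbital-low genes.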

How the results depend on the processing

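The covariates for sex and progenitor score and the restriction to autosomal genes were added after the data were seen. Fold changes were followed for Rarb, Rxrg and the genes named among those past the threshold in a dKO or control comparison, and not for genes named for the lowest p without passing, or named only as list members or for the interaction. None of those followed changed sign, and apart from leaving out samples 501 of their results kept their side of the threshold, 90 lost it and 8 gained it. Counts are given in the order orbital, medial, dorsal and regions summed. Main counts were 7, 389, 4 and 5. DESeq2 gave 430, 1118, 81 and 359. Without a low-count filter they were 122 in orbital, 26 in dorsal and 65 in summed data. With limma-voom they were 12, 688, 3 and 3, and without the prefix 3, 156, 2 and 3. A block for the set gave 14 in orbital and 662 in medial data. The region's own 6 libraries gave 2, 31 and 2, and a threshold of 0.01 gave 3, 68 and 2. Summed data gave 1269 as the mean of the 3 contrasts and 256 with the row as a random effect. The progenitor score gave 2, 1, 2 and 0 (edgeR, 3533 at unadjusted p under 0.05 for the last), and the sex covariate 17, 156 and 9. Without single samples the counts ran from 3 to 8, 67 to 362, 2 to 4 and 4 to 9. The interaction (23) was 0 with RLE size factors, without the row block and at 0.01 (edgeR, 3018, 1286 and 2998 at unadjusted p under 0.05), 1217 with DESeq2, 1401 without a filter, and 0 to 184 without single rows. In controls, medial against dorsal tissue (92) gave 356 with DESeq2 and without a filter, 11 at 0.01, 1 without the row block and 7 to 54 without single rows. Orbital against dorsal (2965) gave 920 at 0.01, 326 without the row block and 923 to 2561 without single rows. Medial against orbital (1690) gave 2921 with DESeq2, 143 at 0.01, 19 without the row block and 599 to 1407 without single rows. Fewer calls at 0.01 follow from the threshold, and for the other shifts the cause was not tested. With an estimated correlation 0 of the 36 lists passed in any dKO comparison (camera, 0, 5, 2 and 1 lists at unadjusted p under 0.05). With fry the counts were 0, 4, 0 and 0 (7, 9, 2 and 4 at unadjusted p under 0.05), against 11, 10, 7 and 6 with the preset. The 4 with fry were cell cycle (adjusted p = 0.00249), radial glia (0.00369), presynaptic release (0.00366) and rostral patterning (0.0172; 3 of 15 higher). Without single rows 5 to 8 lists passed in summed data. The medial and dorsal correlation was 0.742 over genes of at least 5 CPM, and without single sets r ran from 0.404 to 0.490 for it, 0.309 to 0.353 for orbital and dorsal and 0.288 to 0.349 for orbital and medial effects. The retention ratio, with single sets left out, ran from 0.340 to 0.555 for orbital and dorsal, 0.982 to 1.3 for medial and dorsal, and -0.222 to 0.294 for medial and orbital tissue. With 50 and 200 genes per direction it was 0.434 and 0.361, 1.05 and 1.44, and 0.119 and 0.0932 in the same order. The share of changed genes near the loci was 0.314% within 10 Mb and 0.493% within 20 Mb.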

Other observations

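The 4 predicted genes that were higher in dKO in orbital, medial, dorsal and summed data were described after their values were seen. On chromosome 14 lay Gm6356 (6965449 to 6973818), with a mean of 33.3 CPM in dKO and at most 0.0345 CPM in any control library, Gm3373 (5718336 to 5741577), with 1.78 and at most 0.0974 CPM, and Gm10340 (3133997 to 3141609), with 1.21 and at most 0.0315 CPM. On chromosome 3 lay Gm10704 (88576410 to 88577139), with a mean of 7.15 CPM in dKO and at most 0.227 CPM in any control. The lowest dKO library held 15.6 CPM of Gm6356 and 3.70 CPM of Gm10704. Reads shared between near-identical gene copies were not examined.

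The score of progenitor and cell cycle genes (mean log2 CPM) was higher in dKO in 8 of 9 pairs of the same set and region, the exception being dorsal tissue of set A (-0.018). It was 4.0 ± 0.186 in medial controls and 5.25 ± 0.338 in medial dKO (SD, n = 3), 4.38 ± 0.247 and 4.91 ± 0.337 in orbital tissue, and 3.98 ± 0.480 and 4.48 ± 0.0457 in dorsal tissue. In sets A, B and C the score differed by 1.52, 0.796 and 1.42 in medial and 0.713, 0.438 and 0.424 in orbital tissue. Dorsal tissue gave -0.018, 0.635 and 0.892. Set A, where Rarb and Rxrg differed least, thus had the largest score difference in medial and orbital and the smallest in dorsal tissue. Of the 36 lists, 17 passed in no dKO comparison by camera, among them markers of layer 5 (lowest adjusted p = 0.0983), layer 6 (0.0774), subplate (0.0983), interneurons (0.0983), oligodendrocytes (0.0983), choroid plexus (0.135), blood (0.108), olfactory bulb (0.514), thalamus (0.108) and septum (0.0794). Rostral and caudal patterning genes (0.111 and 0.259), ephrins (0.297), genes responsive to retinoic acid (0.249), immediate early genes (0.15), hypoxia genes (0.0983) and heat shock genes (0.111) did not pass either.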
